A study of Mus musculus with 3 samples.

How the data were processed

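The 3 GEO samples of the series are the libraries of 1 droplet pool: RNA, antibody tags for 35 surface proteins, and hashtags that mark 8 samples. Per the labels' protocols, brains were digested, brain cells were enriched on Percoll, blood was freed of red cells, and RNA was prepared with the 10x 3' v3 assay. Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 3.1 and analysed with Seurat 3.1.1. The authors deposited 3 matrices, for the naive brain, the brain with metastases and the blood of mice with metastases, with tables of cell annotation for the first and last. Per the labels, the mice of both arms received tamoxifen and diphtheria toxin.

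The deposited matrices hold the natural log of 1 plus a UMI count that the authors had corrected for depth, which is the data slot of the Seurat SCTransform assay, corrected in each matrix separately. This was checked on the values: after the natural log was undone, 100% were whole numbers within 1e-06 in each matrix, and the sums equal the corrected totals of the deposited annotation in all 2653 cells of the naive brain and all 2924 of the blood. The plan had assumed raw counts, and the corrected UMIs were used in their place. Correction moved molecules as well as scale, since 35.3% of cells in the naive brain and 27.7% in the blood had more detected genes after it than before. Raw UMI counts per cell, antibody totals, hashtag totals, surface gates, clusters and arms were taken from the deposited annotation, in which 36 columns were not used. Antibody tags were used only through the authors' gates.

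The matrices had 17129 genes in the naive brain, 18935 in the brain with metastases and 16619 in the blood, with medians of 9613, 13647 and 5118 corrected UMIs and 2738, 3308 and 1813 genes per cell. Raw UMIs per cell ran from 600 to 512965 in the naive brain. Samples were grouped by the arm that the annotation gives to each hashtag. That left 4 hashed samples by arm, 1 per arm and tissue. The 5933 cells of the brain with metastases formed 1 pooled sample.

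All deposited cells were kept. No doublet caller was run, because raw counts were not used, and droplets listed in more than 1 matrix were counted. For the naive brain and the blood the authors' clusters were named from fixed marker lists. A name needed at least 3 markers at 0.5 CP10k or more and at least 2 fold over the other cells, and no other type with more markers among the 10 leading genes. Other clusters stayed unnamed. The brain with metastases was clustered here with scanpy 1.11.5 and igraph 0.11.9: 2000 variable genes, 30 principal components (scikit-learn 1.9.0), 20 neighbours and Leiden resolution 1.0, with 0.5 and 2.0 as alternatives. Classes also came from marker scores, with a minimum score of 0.3. Clusters of the same name form a class, and a compared class needed at least 30 cells on each side. Expression was compared for microglia, T cells, NK cells and monocytes between the arms of the naive brain, and for neutrophils, B cells, T cells and both monocyte classes between those of the blood. The brain with metastases was compared with the naive brain for microglia, T cells, NK cells and both monocyte classes, and with the blood for T cells and both monocyte classes. Other classes large enough, such as neutrophils and vascular cells of the naive brain, were not compared for expression, apart from their Cx3cr1 level.

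Corrected UMIs were summed over the cells of a class and scaled to 10000, giving CP10k. The log2 ratio of each gene used a pseudocount of 0.1 CP10k, and a gene counted as measured at 0.5 CP10k or more in at least 1 side. Ratios between arms were taken within a matrix. The comparisons of the brain with metastases with the naive brain and with the blood cross matrices that were normalized separately. The 4 comparisons gave 17 comparisons by class. Sums over cells of 1 sample carry no spread between mice, so no test was made, no p-value is given and no genes were called changed. Members of a list past 2 fold are counted as a description. Shares carry exact Clopper-Pearson 95% intervals, and ratios of shares an exact interval conditional on the summed cells. For each of 24 gene lists, written before the data were examined, the median log2 ratio of the measured members was placed among 10000 random lists drawn from the same 20 bins of expression, as a description. The members of a list are not independent, so that percentile is not a p-value.

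Genes were named by rule: the 10 highest and 10 lowest log2 ratios of measured genes in each class, from which the text takes some, any member of the fixed lists, and a short set of genes fixed in advance that includes Cxcl10, Cd274, Vsir, Cx3cr1, P2ry12 and Tmem119. Mitochondrial and ribosomal protein genes, names starting with Gm or a digit or ending in Rik, haemoglobin, immunoglobulin and T cell receptor genes, Xist and Y-linked genes were not named by size. No gene coordinates were used.

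The procedure was tested on simulated data made from the naive brain microglia, depleted against control, with 686 and 134 cells. Of 3119 genes 200 were changed. Genes set to be doubled had a median log2 ratio of 0.90, genes set to be halved -0.99, and unchanged genes -0.07. A list of doubled genes stood at percentile 100 and an unchanged list at 87.4. The simulated cells came from a common profile with counting noise only. They held no differences between cells or mice, no shared droplets and no carry-over, so the test covers the arithmetic and not those effects.

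Alternatives were the low-gene filter (none, or 1 CP10k), a pseudocount of 0.01 CP10k, the mean over cells of each cell's own CP10k, a mean trimmed by 2% of cells at each end, leaving out cells with fewer than 0.4 or more than 2.5 times the class median of genes, other denominators of shares, the authors' earlier annotation table, and lists without genes of other lists. After the data were seen, leaving out shared droplets, surface gates in place of clusters, gated cells as the denominator, single arms of the naive brain and leaving out a cycling T cell cluster or microglial cluster 1 of the brain with metastases were added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.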

Results

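Microglia are the resident macrophages of the brain, and the study asked how they shape the immune cells around brain metastases of a breast cancer line. Cells were profiled with CITE-seq, which reads RNA and antibody-tagged surface proteins from the same droplet. All mice carried Cx3cr1CreERT, a tamoxifen-switched recombinase under Cx3cr1, a chemokine receptor gene of microglia and monocytes. The mice of the depleted arm also carried ROSA-iDTR, a Cre-dependent receptor for diphtheria toxin, so that the toxin kills recombined cells. Control mice received the same drugs. Metastases grew from E0771, a mouse mammary tumour line, injected into the carotid artery. Brain suspensions had been enriched for immune cells on a Percoll gradient, so a share of recovered cells is not a density in the tissue, and the submitters state that some microglia remain in depleted samples.

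Each of 8 samples carried its own hashing antibody, and all were loaded as 1 pool. The naive brain gave 785 cells in the sample labelled control and 1868 in the sample labelled depleted, with median raw UMI counts (captured RNA molecules) of 8621 and 10119.5 per cell. The blood of mice with metastases gave 1371 and 1553 cells, with medians of 4571 and 5885. Summed raw UMIs were 15811707 and 39400503 in the naive brain and 27311805 and 29587041 in the blood, control first. The brain with metastases held 5933 cells, which entered as 1 pooled sample because no map from its cells to the arms was used here. The effect of depletion in that brain, and any difference of it from the naive brain, was therefore not analysed here. With 1 hashed sample per arm and tissue there was no replicate and no test. Intervals are exact 95% Clopper-Pearson intervals for shares and conditional exact intervals for their ratios, and cover counting error only. Expression is given as CP10k, UMIs per 10000 depth-corrected UMIs of all cells of a class. A gene list is described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists matched on expression.

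Cx3cr1 went against the labels. In microglia of the naive brain it reached 10.0 CP10k in the sample labelled depleted and 1.72 CP10k in the sample labelled control, a log2 ratio of 2.48. In the blood it was higher under the depleted label in nonclassical monocytes (3.64 against 0.286 CP10k, log2 ratio 3.28) and in classical monocytes (2.15 against 0.170 CP10k, log2 ratio 3.06). Among the 8 classes with enough Cx3cr1 to compare, 7 were at least 2-fold higher in the sample labelled depleted. The exception was a microglia-like cluster of the blood, with 5.86 against 5.03 CP10k. The classes that were higher include vascular cells (1.46 against 0.663 CP10k) and neutrophils (1.43 against 0.268 CP10k) of the naive brain. Whether Cx3cr1 was carried over into them from microglia or monocytes was not tested, so the classes may not be independent. Without droplets listed in more than 1 matrix, 6 classes had enough cells and Cx3cr1, and 3 of them were at least 2-fold higher. Microglia of the brain with metastases, in a matrix normalized separately, held 7.32 CP10k. The share of microglia in the naive brain was also higher in the sample labelled depleted, at 36.7% against 17.1%. Both arms carry the Cre allele, so Cx3cr1 RNA does not by itself tell which arm carried the toxin receptor. Samples are named by their labels throughout, and every direction between arms is that of the labels.

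**Figure D1:**
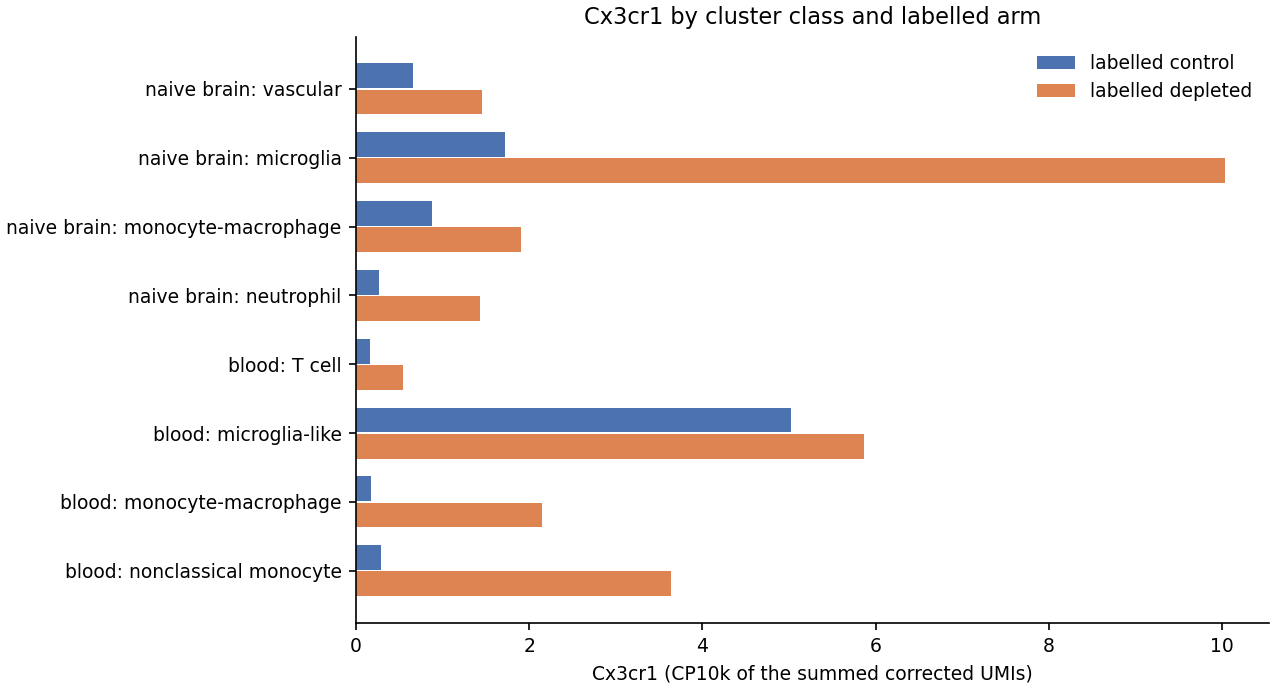
Cx3cr1 level, in CP10k of the summed corrected UMIs, by cell class of the naive brain and the blood, with blue bars for samples labelled control and orange bars for samples labelled depleted. The orange bar is longer in each class. As a ratio, the pair of the blood microglia-like cluster differs least, at 5.86 and 5.03.

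Many droplets were listed in more than 1 of the 3 matrices. The naive brain and the blood shared 339 cell barcodes, the brain with metastases shared 578 with the blood and 518 with the naive brain, and 84 were in all matrices. Raw RNA totals and antibody totals were equal in all 339 barcodes shared by the naive brain and the blood, so these are taken as the same droplets. Hashtag totals were equal in 0 of them. Cells were called to hashtags 1 and 4 in the naive brain and to 7 and 8 in the blood. A shared barcode was thus called to a hashtag of both tissues, and the totals are likely to count different hashtags, which was not tested further. Shared barcodes made up 29.1% of the cells of the naive brain, 28.5% of the blood and 17.1% of the brain with metastases. They were unevenly spread, with 62.2% of monocyte cluster 3 and 65.7% of neutrophil cluster 7 in the naive brain, and 82.7% of microglia-like cluster 2 and 49.0% of T cell cluster 5 in the blood. The deposited cells were all kept in the values below. No doublet caller was run, and some of the values that moved without the shared droplets are given below.

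**Figure D2:**
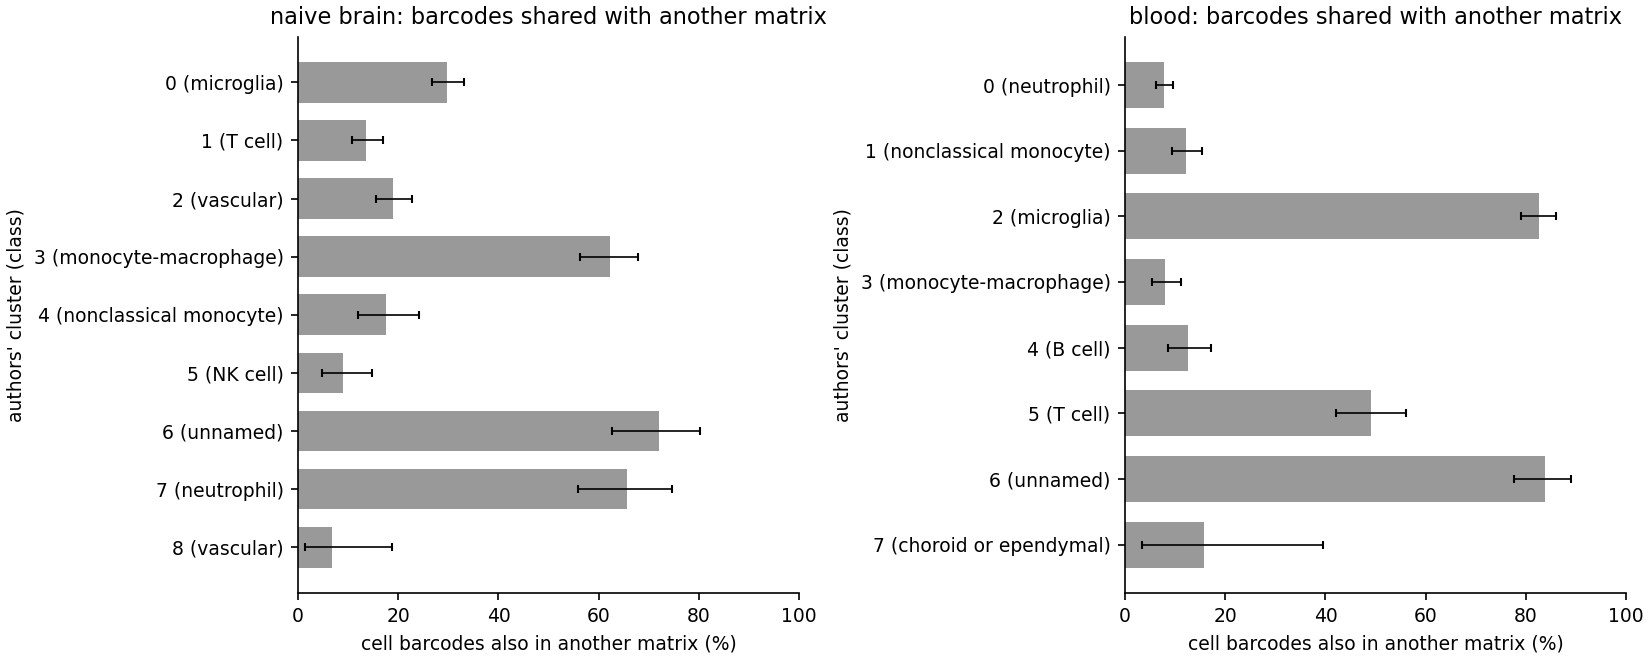
Percent of the cell barcodes of each authors' cluster that are also listed in another matrix, for the naive brain (left) and the blood (right), with class names in brackets and 95% exact intervals. Blood clusters 2 and 6 stand at 82.7% and 83.9%, against 7.66% for blood neutrophil cluster 0.

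In the naive brain, T cells took a larger share in the sample labelled depleted. By the authors' surface gates, all CD3+ T cells were 12.9% against 4.33% of cells, a ratio of 2.98, and CD8+ T cells were 7.50% against 1.78%, a ratio of 4.20 (2.42 to 7.89). CNS-native myeloid cells, the gate that holds microglia, were 51.2% against 38.2%, a ratio of 1.34, and NK1.1+ cells were 6.48% against 4.33%. Myeloid cells of blood type were lower. The CD11b+ Ly6C-low gate held 6.42% against 19.5%, a ratio of 0.330 (0.257 to 0.421), and the CD11b+ Ly6C+ Ly6G+ gate, which takes neutrophils, held 2.94% against 7.52%, a ratio of 0.392 (0.266 to 0.576). The B220+ gate did not differ beyond counting error, at 3.64% against 5.22%, and its ratio of 0.697 turned to 1.08 without shared droplets.

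The authors' clusters gave the same directions for microglia, T cells, nonclassical monocytes and neutrophils, while NK cells (cluster 5) did not differ beyond counting error, at a ratio of 1.28 (0.874 to 1.93). Microglia (cluster 0) had a ratio of 2.15 (1.79 to 2.61) and T cells (cluster 1) a ratio of 3.13 (2.38 to 4.19). Nonclassical monocytes (cluster 4), which patrol vessels, were 0.964% of the sample labelled depleted and 18.9% of the sample labelled control, 19.6 times as much under the control label. Monocytes (cluster 3) had a ratio of 0.651 and neutrophils (cluster 7) 0.480. Cluster 2, with a low median of 2436 raw UMIs per cell, was 15.3% against 24.7%, and is called vascular here, with cluster 8, because it carried 5 endothelial markers and was led by Mgp, Tagln and Acta2, genes of the muscle of vessel walls. An unnamed cluster of very deep cells (cluster 6, led by Rhox5, Wfdc2 and Krt8) made up 4.71% and 2.93% of cells. Each share moves the others, since all are parts of 1 total. Median hashtag counts per cell were 215 under the control label and 837.5 under the depleted label. Under the control label they were 113, 63 and 81.5 in clusters 7, 3 and 2, against 390.5 in cluster 4 and 666 in cluster 1. Under the depleted label clusters 7, 3 and 2 had 832.5, 1132 and 398. Cells called on stray hashtag may raise the control shares of clusters 7, 3 and 2, which was not tested.

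**Figure D3:**
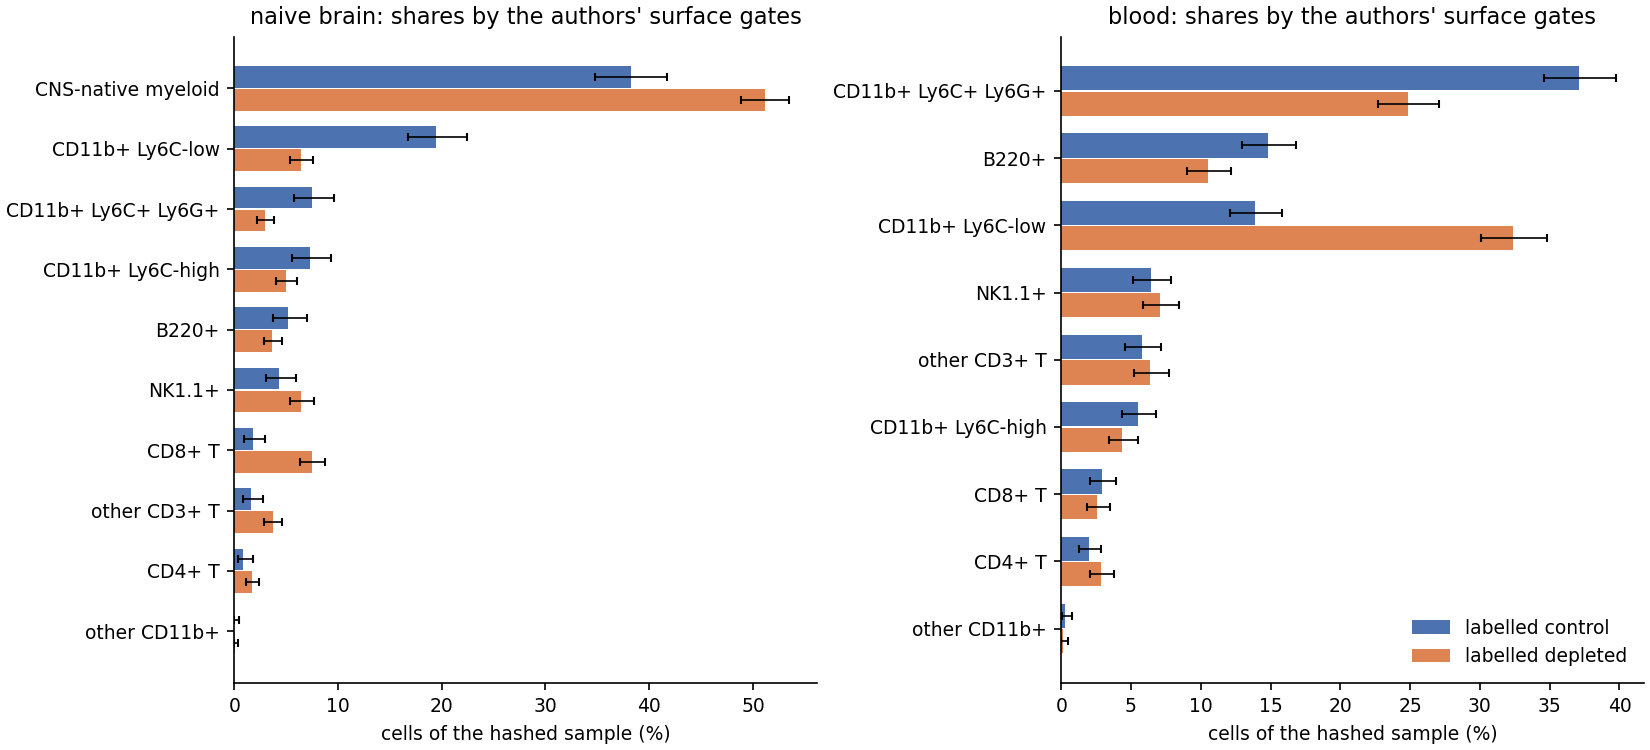
Share of cells, in percent of each hashed sample, by the authors' surface gates in the naive brain (left) and the blood (right), for samples labelled control (blue) and depleted (orange), with 95% exact intervals. The CD11b+ Ly6C-low gate was lower under the depleted label in the naive brain (6.42% against 19.5%) and higher in the blood (32.4% against 13.9%).

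Microglia of the naive brain (686 cells labelled depleted, 134 labelled control) kept close levels of the identity genes other than Cx3cr1. P2ry12, a purine receptor, stood at 9.31 against 9.96 CP10k, and Tmem119 at 7.11 against 7.65. Inflammatory genes were lower in the sample labelled depleted. Of 14 measured chemokines 12 were lower, with a median of -0.49 (percentile 0), and of 9 inflammatory cytokine genes 8 were lower, with a median of -0.37 (percentile 0.13). Il1b, the main secreted interleukin-1, had a log2 ratio of -1.05, Ccl4 was at 34.7 against 46.7, and Cxcl13, a B cell attractant, at 0.0146 against 1.89. All 17 measured dissociation and immediate early genes were lower too, with a median of -0.34 (percentile 0). The interferon response list had a median of -0.13 (percentile 9.21) that turned to 0.08 with classes from marker scores, and Cxcl10, an interferon-induced chemokine, was at 6.05 against 6.10. The disease-associated list was at 0.08 (percentile 75.4). The homeostatic list was at -0.10 (percentile 5.29), and at 0.28 with surface gates.

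Some genes named by size in these microglia are better known from other blood cells. Prss34 and Mcpt8, basophil proteases, were at 1.54 and 0.616 CP10k and listed at 0 in the sample labelled control. Nkg7, a cytotoxic granule gene, had a log2 ratio of 1.60. BC100530, G0s2 and Ly6d were lower, with log2 ratios of -2.66, -1.92 and -1.74. Haemoglobin genes were far higher in the sample labelled depleted, with a median of 4.96 over 4 genes, and the neutrophil carry-over list was lower, at -0.57 (percentile 0.01). MHC class II genes had a median of -0.29 (percentile 0.52), which turned to 0.32 when classes were taken from marker scores, and Cd74, their chaperone, had a log2 ratio of -0.40. Vsir stood at 4.69 against 4.80 CP10k and Cd274, which encodes PD-L1, at 0.237 against 0.422. Ly6d and BC100530 turned direction in an alternative class definition, and Cx3cr1 reached a log2 ratio of 3.93 without shared droplets.

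T cells of the naive brain (cluster 1, 440 and 59 cells) had lower interferon-response genes in the sample labelled depleted. Of 18 members 17 were lower, with a median of -0.49 (percentile 0). Isg15, a ubiquitin-like protein, was at 2.13 against 3.70 CP10k, and Cxcl10 at 1.03 against 4.42. The effector list had members going both ways, 6 higher and 5 lower, with a median of 0.32 (percentile 100). Gzmk, a granzyme, was at 1.82 against 0.770 CP10k and Ccl5 at 69.2 against 55.5. All 7 measured genes of the naive and memory list were lower, with a median of -0.42 (percentile 0.105), and Il7r, the interleukin-7 receptor, was at 1.61 against 3.43. Ptpre had a log2 ratio of 1.39, and Pxdc1 and Il17a had ratios of -1.85 and -1.63. Genes of microglia moved in these T cells as well. The homeostatic microglia list had a median of 0.74 and the lysosome and phagocytosis list 0.53, each at percentile 100, and Apoe and C1qa had log2 ratios of 1.31 and 1.26. Mitochondrial transcripts were at -0.17 (percentile 0.14). Apoe turned lower in T cells taken by surface gate, where the lysosome list was at -0.38.

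NK cells of the naive brain (cluster 5, 110 and 36 cells) went the other way for interferon-response genes, with a median of 0.37 over 14 members (percentile 99.98). Cxcl10 was at 2.52 against 0.457 CP10k and Isg15 at 1.73 against 0.701. Ifit1 rested on 85 and 2 corrected UMIs. Cell cycle genes Ube2c and Cenpf had log2 ratios of -2.62 and -2.28, and Rgs16, a signalling regulator, -2.14. Dcn, a matrix gene of fibroblasts, was at 0.574 CP10k and listed at 0 in the sample labelled control. The neutrophil carry-over list was higher, at 1.34. Cenpf turned direction when cells far from the class median of detected genes were left out. With 36 cells labelled control, these levels rest on few molecules.

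Monocytes and monocyte-derived macrophages of the naive brain (cluster 3, 172 and 111 cells) had lower interferon and inflammatory genes in the sample labelled depleted. All 25 measured interferon-response genes were lower, with a median of -0.50 (percentile 0). All 14 chemokines were lower too, with a median of -0.50 (percentile 0.03), as were all 11 inflammatory cytokine genes, with a median of -0.46 (percentile 0.03). Irf7, a transcription factor of the interferon response, was at 4.09 against 8.13 CP10k, Il1b at 26.3 against 44.5 and Cxcl10 at 12.7 against 15.6. Cx3cr1 was at 1.90 against 0.873 CP10k, and at a log2 ratio of 0.09 without shared droplets. The median hashtag count of this cluster was low in the sample labelled control, at 63 against 248.5 in its other clusters. In the sample labelled depleted it was 1132 against 784.5. With 62.2% of the barcodes also in another matrix, some of these cells may belong to other samples, which was not tested.

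MHC class II genes were higher in these monocytes under the depleted label, with a median of 0.85 (percentile 100), and H2-Aa was at 55.0 against 29.1 CP10k. The list turned lower with classes from marker scores, at -0.23, and with surface gates. Mgl2, Cd209a and Clec4b1, lectin genes of antigen-presenting cells, had log2 ratios of 2.98, 1.72 and 1.49. Prg4, a lubricating proteoglycan, was at 0.00569 against 1.11 CP10k, G0s2 at 0.154 against 2.16 and Serpinb2 at 0.0512 against 0.665. The neutrophil carry-over list had a median of -1.05 (percentile 0). Mgl2, Cd209a and Prg4 turned direction with surface gates, and Clec4b1 with marker scores.

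In the blood, nonclassical monocytes were more frequent under the depleted label and neutrophils and B cells less so. The CD11b+ Ly6C-low gate held 32.4% against 13.9% of cells, a ratio of 2.34 (1.97 to 2.78), and nonclassical monocytes (cluster 1) were 24.9% against 6.93%, a ratio of 3.59 (2.86 to 4.54). With the authors' earlier annotation table in place of the updated one, the gate had a ratio of 1.42. The CD11b+ Ly6C+ Ly6G+ gate held 24.9% against 37.1%, a ratio of 0.670 (0.585 to 0.766), and neutrophils (cluster 0) had a ratio of 0.705 (0.620 to 0.802). The B220+ gate held 10.5% against 14.8%, a ratio of 0.709 (0.573 to 0.875), and B cells (cluster 4) had a ratio of 0.603. T cells, NK1.1+ cells and Ly6C-high monocytes did not differ beyond counting error by gate, and the ratio of all CD3+ T cells was 1.11 (0.885 to 1.39). Without shared droplets the ratio of CD8+ T cells turned from 0.883 to 1.82 and that of NK1.1+ cells turned below 1, to 0.749. A microglia-like cluster (cluster 2, 10 microglial markers) made up 15.1% and 17.1% of blood cells, and the unnamed cluster of deep cells (cluster 6) 5.99% and 6.35%.

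Neutrophils of the blood (429 and 537 cells) had lower interferon-response genes in the sample labelled depleted. Of 15 members 13 were lower, with a median of -0.91 (percentile 0). Ifi27l2a was at 2.56 against 13.6 CP10k and Ifitm3, a barrier to virus entry, at 10.3 against 15.9. Slfn5 and Ifit3 had log2 ratios of -1.74 and -1.62, and Isg15 -0.59. Chil3, a chitinase-like protein of myeloid cells, was higher at 2.48 against 0.308 CP10k, and Asnsd1 had a log2 ratio of 1.03. All 15 measured dissociation and immediate early genes were higher, with a median of 0.30 (percentile 100).

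Nonclassical and classical monocytes of the blood showed lower interferon-response genes under the depleted label as well. In nonclassical monocytes (386 and 95 cells) 12 of 13 members were lower, with a median of -0.81 (percentile 0), and in classical monocytes (cluster 3, 195 and 160 cells) 16 of 18, with a median of -0.73 (percentile 0). Ifi27l2a was at 3.18 against 16.1 CP10k in the former and 11.5 against 32.7 in the latter. Oasl2 in the former had a log2 ratio of -2.13, and Isg15 and Ifi206 in the latter had ratios of -1.55 and -1.80. Cxcl10 did not follow in classical monocytes, at 1.03 against 0.837 CP10k. MHC class II genes were lower in nonclassical monocytes, with a median of -0.82 (percentile 0) and Cd74 at 5.54 against 12.7 CP10k, while in classical monocytes the list was at -0.16 (percentile 7.32).

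Besides Cx3cr1, nonclassical monocytes labelled depleted had more Pecam1, an adhesion molecule, at 1.58 against 0.286 CP10k, and more Saa3, an acute-phase protein, which was listed at 0 under the control label. Areg, an epidermal growth factor family ligand, had a log2 ratio of -2.80 and Cd274 a ratio of 0.52. In classical monocytes Lpl, lipoprotein lipase, was at 1.56 against 0.127 CP10k, Ccl5 had a log2 ratio of -1.71, and Prg4 rested on 132 and 2 corrected UMIs. In the nonclassical class the neutrophil carry-over list was lower too, with a median of -1.28 (percentile 0.01), as were 14 of 15 dissociation and immediate early genes, with a median of -0.36 (percentile 0). Haemoglobin genes there had a median of -5.87, and mitochondrial transcripts -0.53 (percentile 0.03), which turned to 0.40 with marker scores. Areg and Ccl5 turned direction with surface gates, and Cx3cr1 in nonclassical monocytes was at a log2 ratio of 1.75 with them.

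B cells and T cells of the blood differed less in this respect. In B cells (101 and 148 cells) all 8 measured interferon-response genes were lower under the depleted label, with a median of -0.51 (percentile 0.03). This turned to 0.48 with surface gates and to 0.67 with marker scores, and Isg15, with a log2 ratio of -1.55, turned with both. Jchain, which joins secreted immunoglobulin chains, had 1 corrected UMI against 1351, Il17a was listed at 0 against 0.833 CP10k, and Chil3 was at 1.23 against 0.0847. Mitochondrial transcripts in B cells had a median of -0.38 (percentile 0.04) and the neutrophil carry-over list 1.05 (percentile 100). The T cell class of the blood (cluster 5) was led by Gzma, Nkg7 and Ccl5, genes shared with NK cells, and no blood cluster was named NK. Of its 206 cells 178 had a transcript of Cd3d, Cd3e or Cd3g, 126 lay in the T cell gates and 13 in the NK1.1+ gate, while 19 had Ncr1 or Klrb1c, NK cell genes, and no Cd3 transcript. In this class (103 and 103 cells) the interferon list was at -0.10, within its random lists, and at 0.06 with marker scores, and mitochondrial transcripts were at -0.35 (percentile 0). Ttr and Enpp2, genes of the choroid plexus, had log2 ratios of 3.77 and 3.47 there, Il17a and Pou3f1 were each listed at 0 on 1 side, and Gadd45g had a ratio of -2.20. Ttr, Gadd45g, Jchain and Chil3 in these classes turned direction in at least 1 alternative.

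**Figure D4:**
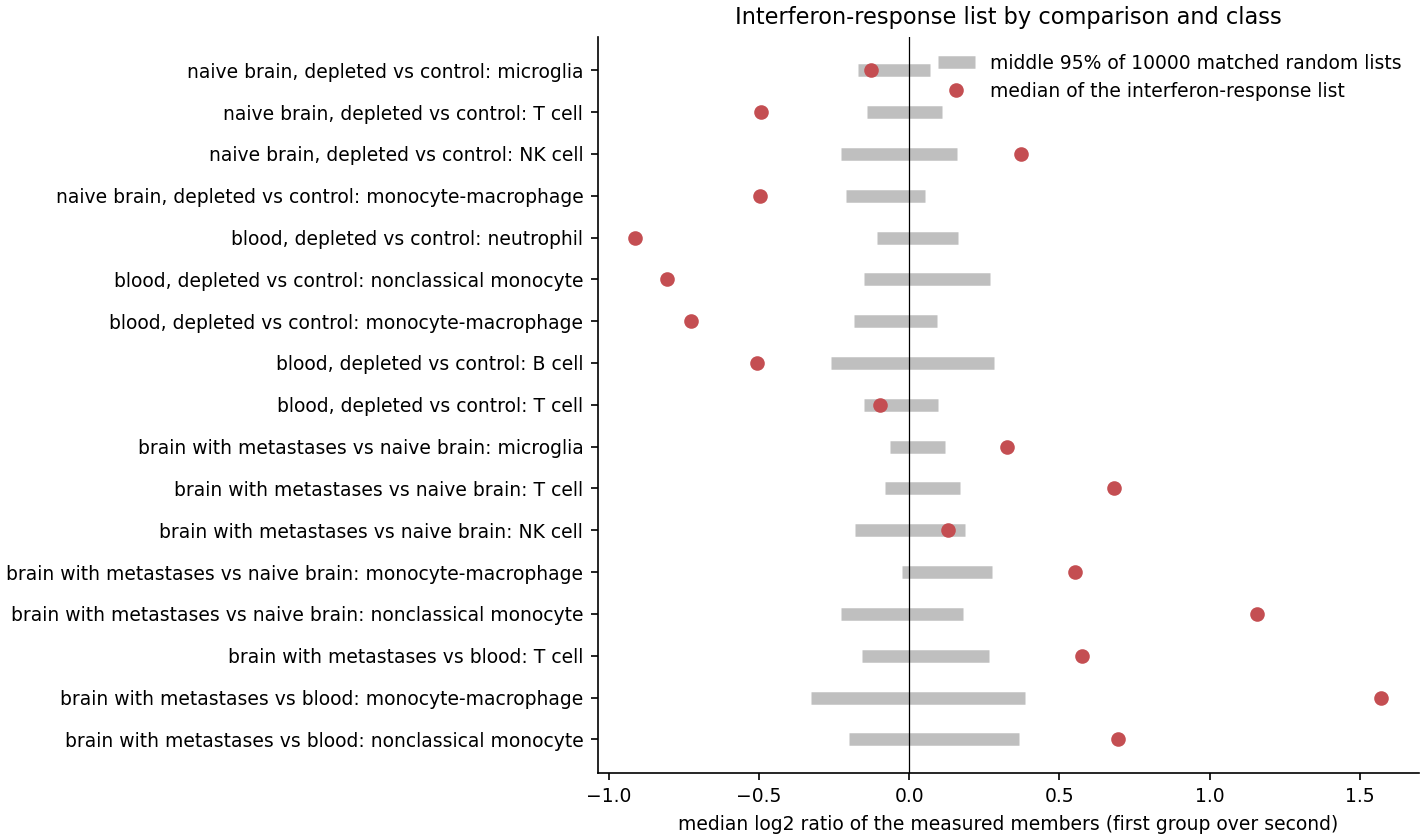
Median log2 ratio of the interferon-response list (red points, first-named group over the second) for each comparison and class, with the middle 95% of 10000 matched random lists in grey. Blood neutrophils (-0.91) and both blood monocyte classes lie to the left of their grey bars, and each class of the brain with metastases lies to the right of 0.

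The brain with metastases was set against the naive brain with both arms of the latter together. The 2 matrices were normalized separately, and its classes come from a clustering made here. Microglia (clusters 1, 2 and 19) were 12.3% of cells against 30.9%, a ratio of 0.398 (0.359 to 0.440). Cluster 1, with 170 of these cells, carried 9 microglial markers, but none was among its 10 leading genes, such as Cxcl13, Apoe, H2-Eb1 and Mgl2, and 44.7% of its barcodes were in another matrix. The ratio was 0.314 without it. Nonclassical monocytes (cluster 21) were 2.36% against 6.26%. T cells (clusters 8, 16 and 17) were 13.1% against 18.8% and NK cells (cluster 6) 3.37% against 5.50%. Monocytes and monocyte-derived macrophages (clusters 3 and 4) were 14.6% against 10.7%, a ratio of 1.37 (1.20 to 1.57), and neutrophils (clusters 13 and 22) 4.13% against 3.96%. Unnamed clusters held 33.2% of the brain with metastases and 4.18% of the naive brain, which lowers every other share of the former. Of these, clusters 0, 10 and 27 had Krt8 alone of the E0771 tumour markers. Clusters 7, 15 and 26 held 19.5%, 27.2% and 46.9% mitochondrial UMIs. Cluster 5, with 10 microglial markers, was unnamed too and is not counted as microglia. Among immune classes only, the ratio was 0.556 for microglia, 0.974 for T cells, 0.857 for NK cells, 0.527 for nonclassical monocytes, 1.91 for monocytes and 1.46 for neutrophils, so the T cell difference was nearly gone. The microglial ratio was 0.720 against the sample labelled control alone and 0.335 against the sample labelled depleted alone. The monocyte ratio was 2.42 without shared droplets and turned below 1 at other clustering resolutions, where names changed. Ms4a7 and Fabp5, leading genes of cluster 3, were among those of clusters of 238 and 115 cells at resolution 2.0, named border macrophage. At 0.5 they were among those of an unnamed cluster of 876 cells. Part of this class, also compared for expression below, thus has no firm name. The T cell ratio turned to 1.74 against the sample labelled control alone. The nonclassical ratio was 0.125 against that sample and 2.45 against the sample labelled depleted, and the neutrophil ratio 0.662 and 1.38.

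Microglia of the brain with metastases had higher inflammatory genes than those of the naive brain (729 and 820 cells), by an amount that depended on the cells compared. Of 19 interferon-response genes 15 were higher, with a median of 0.33, of 13 chemokines 12, with a median of 0.50, and all 9 inflammatory cytokine genes, with a median of 0.57, each at percentile 100. Cxcl9, an attractant of T cells, was at 1.17 against 0.326 CP10k, Gbp2 at 0.890 against 0.282, Isg15 at 2.52 against 1.37 and Cxcl10 at 7.90 against 6.06. All 20 homeostatic genes were lower by a small amount, with a median of -0.19 (percentile 0), and P2ry12 was at 7.57 against 9.42. Cx3cr1 was at 7.32 against 8.70 CP10k, but had a log2 ratio of 2.03 against the sample labelled control alone. Thbs1, a matrix glycoprotein, had a log2 ratio of 1.68, and the monocyte origin list a median of 0.79 (percentile 100). Of the naive microglia 686 were from the sample labelled depleted. Against the sample labelled control alone the interferon median was 0.09, that of chemokines 0.17 and that of inflammatory cytokines 0.29. Without cluster 1, and with no cells left out of the naive brain, these medians were -0.16, 0.22 and 0.50, that of the homeostatic list was -0.04 and that of the monocyte origin list -0.62, and Cxcl9, Gbp2 and Thbs1 turned lower. Because cells were left out on 1 side only, these values do not settle whether the higher interferon, Cxcl9 and monocyte origin genes rested on cluster 1.

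Of the checkpoint genes, Vsir was lower in these microglia, at 4.13 against 4.71 CP10k. Cd274 was at 0.363 against 0.267 CP10k, too low on both sides to count as measured. In naive microglia labelled control, Cd274 was at 0.422 CP10k and Vsir at 4.80, both above the brain with metastases. In those labelled depleted, Cd274 was at 0.237 and Vsir at 4.69. The direction of Cd274 thus depended on the arm of the naive brain. The myeloid suppression list had a median of 0.01 (percentile 28.8) and the MHC class I list 0.08 (percentile 48.1). The MHC class II list was at 0.09 (percentile 44.7), with 6 of 7 members higher, but at -3.22 without cluster 1. Tmem119 had a log2 ratio of -0.21. The neutrophil carry-over list was far lower, with a median of -3.30 (percentile 0), S100a9 and S100a8, calcium-binding proteins of neutrophils, had log2 ratios of -4.17 and -4.04, and Jchain had a ratio of -4.73. With classes from marker scores these 3 genes and that list were higher. Cluster 5 of the brain with metastases, 114 cells with 10 microglial markers but led by Stfa1, Stfa2 and Cxcr2, stayed unnamed and outside these microglia. Of its barcodes 72.8% were in another matrix. The naive microglia are a whole cluster of the authors, so such cells may have stayed on the naive side only, which was not counted.

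T cells of the brain with metastases (777 cells against 499) had higher interferon-response genes, all 18 of them, with a median of 0.68 (percentile 100). All 8 cell cycle genes were higher, with a median of 0.72 (percentile 100), but the median was -0.06 without cluster 17, a cycling cluster of 37 cells. The T cells of the naive brain all lie in cluster 1 of the authors, from which no cycling cells were left out. The exhaustion and checkpoint list had a median of 0.35 (percentile 99.8), with 6 of 11 members higher, 4 of them at least 2-fold, but was at 0.05 without cluster 17 and turned to -0.21 with a trimmed mean over cells. Ctla4 was at 2.23 against 0.824 CP10k, Pdcd1, which encodes PD-1, at 0.788 against 0.322 and Tnfrsf9, a costimulatory receptor, at 1.00 against 0.160. Gzmb, a granzyme, was at 5.91 against 2.21, Gzmk had a log2 ratio of -1.08, and the effector list as a whole was at -0.13 (percentile 1.11). Isg15 was at 4.59 against 2.32 and Cxcl10 at 3.39 against 1.44. Ifitm1 and Areg had log2 ratios of 3.13 and 2.88, and Trem2 and Ly86, genes of microglia, -1.25 and -1.14. Ctsk rested on 660 and 1 corrected UMIs.

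The tissue residency list was lower in these T cells, with a median of -0.51 (percentile 0), and haemoglobin genes were higher, at 3.01. Against the sample labelled control alone the interferon median was 0.16 and Cxcl10 turned lower, while against the sample labelled depleted alone that median was 0.74. NK cells (200 against 146) had the residency list at -0.83 (percentile 0), with Cxcr6, a homing receptor, at 1.25 against 3.76 CP10k. Vegfa, a vessel growth factor, and Serpinb9b had log2 ratios of 1.82 and 1.65, and Gzmc and Apoe -1.59 and -2.11. The interferon list of NK cells was at 0.13 (percentile 90.4), and haemoglobin genes were at 5.05.

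Monocytes and monocyte-derived macrophages of the brain with metastases (866 against 283) had all 25 interferon-response genes higher, with a median of 0.55 (percentile 100). Cxcl10 was at 26.2 against 13.8 CP10k and Isg15 at 14.1 against 8.36. The hypoxia and glycolysis list was at 0.55 (percentile 100) and the suppression list at 0.42 (percentile 99.9), with Cd274 at 1.98 against 1.20 and Arg1, arginase, at 0.679 against 0.148. Homeostatic microglial genes were lower, with a median of -1.34 (percentile 0), and Sparc among them had a log2 ratio of -3.03. MHC class II genes were lower, with a median of -0.59 (percentile 0), but were at 0.23 with marker scores and 0.09 against the sample labelled control alone. Against the sample labelled control alone the interferon median was 0.20, that of hypoxia and glycolysis 0.33 and that of suppression 0.18. Against the sample labelled depleted alone these medians were 0.83, 0.71 and 0.40. Without shared droplets the interferon median was 1.18, and haemoglobin genes had a median of 3.68.

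Some genes named by size in this class also lead single clusters. Elane and Mpo, granule enzymes of early myeloid cells, had log2 ratios of 3.57 and 3.67, and Prss34 was listed at 0 in the naive brain; they lead cluster 4 of the brain with metastases. Cd209a and Mgl2 had ratios of -3.15 and -3.11, and lead cluster 20, a dendritic-cell-like cluster kept apart in that matrix only. Elane, Mpo and Cd209a turned direction with marker scores. Nonclassical monocytes (140 against 166 cells) had all 12 interferon-response genes higher, with a median of 1.16 (percentile 100). Isg15 was at 1.66 against 0.432 CP10k, Gbp2 at 0.926 against 0.185, Ly6a at 2.14 against 0.535 and Cxcl10 at 1.86 against 0.665. Of the naive cells 148 were from the sample labelled control. The 3 measured genes of the neutrophil carry-over list were lower beside this, with a median of -2.19, and mitochondrial transcripts were at -0.26 (percentile 0.07).

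Monocyte-lineage cells differed most between the brain with metastases and the blood, whose matrices were also normalized separately. In monocytes and monocyte-derived macrophages (866 and 355 cells) 12 of 14 chemokines were at least 2-fold higher in the brain, with a median of 4.62 (percentile 100). Dissociation and immediate early genes were higher beside them, with a median of 2.33 (percentile 100), and the brain but not the blood was digested. Cxcl9 was at 14.4 against 0.0528 CP10k, Cxcl2, a neutrophil attractant, at 46.7 against 0.456, Ccl2, a monocyte attractant, at 15.9 against 0.125 and Cxcl10 at 26.2 against 0.940. Of 25 interferon-response genes 23 were higher, with a median of 1.57, and the disease-associated list had a median of 2.36, each at percentile 100. Spp1, osteopontin, was at 11.8 against 0.211 and Cd274 at 1.98 against 0.120, and the suppression list was at 1.44 (percentile 99.99). Monocyte origin genes were lower, with a median of -1.21 (percentile 0). Fn1, fibronectin, was at 4.65 against 26.4, Chil3 at 8.98 against 46.3, Hpgd at 0.312 against 2.73 and Vsir at 1.62 against 2.75. Haemoglobin genes had a median of 4.20. With marker scores the chemokine median was 2.91 and the disease-associated median 1.27.

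Nonclassical monocytes of the brain with metastases (140 against 481 cells) had all 12 interferon-response genes higher than those of the blood, with a median of 0.70 (percentile 99.99), and Cxcl10 at 1.86 against 0.468 CP10k. Chemokines had a median of 1.82 (percentile 100) and Ccl4 was at 10.8 against 1.08. All 16 dissociation and immediate early genes were higher in the brain, whose tissue was digested, with a median of 1.60 (percentile 100), Fos at 17.9 against 2.36 and Ccrl2 at 7.42 against 0.944. S100a8 was at 1.65 against 17.6, mitochondrial transcripts had a median of -1.22 (percentile 0) and haemoglobin genes -4.24. The interferon median was 1.90 with marker scores, and the chemokine median 0.00 without a filter on low genes.

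T cells of the brain with metastases (777 against 206 cells) had lower genes of the naive and memory state than blood T cell cluster 5, which also held some cells with NK cell genes. All 10 members were lower, with a median of -1.04 (percentile 0). The exhaustion and checkpoint list was higher, with a median of 0.33 (percentile 99.8) and Ctla4 at 2.23 against 0.957 CP10k. Ifi27l2a was at 20.8 against 8.04 and Odc1, an enzyme of polyamine synthesis, at 4.31 against 1.71, and Ctsk had 660 against 1 corrected UMIs. Neutrophil genes were higher in the blood T cells, where the carry-over list had a median of -4.87 (percentile 0), S100a8 was at 1.27 against 40.1, S100a9 at 1.97 against 59.7 and Retnlg at 0.187 against 12.1. Without shared droplets the checkpoint median was 1.92. Mitochondrial transcripts were lower in the brain T cells, with a median of -0.52, and haemoglobin genes higher, at 2.68.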

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

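The tests of the patterns below were all chosen after the results were seen, while the gene lists, the comparisons and the rules for naming genes and clusters were set before the data were examined. Directions between arms are those of the labels.

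CD11b+ Ly6C-low cells and nonclassical monocytes went opposite ways in the naive brain and in the blood, while the CD11b+ Ly6C+ Ly6G+ gate was lower under the depleted label in both (0.392 and 0.670). The share of the CD11b+ Ly6C-low gate in the sample labelled depleted over that labelled control was 0.330 in the naive brain and 2.34 in the blood, and that of nonclassical monocytes was 0.0511 and 3.59. In the class of monocytes and monocyte-derived macrophages the disease-associated list had a median of -0.39 in the naive brain and 0.14 in the blood. The inflammatory cytokine list was at -0.46 and 0.73. The make-up of this class may differ between the tissues. The difference between the tissues was not tested, since each value rests on 1 hashed sample per arm, and tissue, tumour and mouse differ between them.

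Several cell populations fell outside the comparisons of expression, among them the vascular cells and neutrophils of the naive brain. A cluster with 10 microglial markers made up 16.0% of the blood cells, and an unnamed cluster of very deep cells, led by Rhox5, Wfdc2 and Krt8, made up 4.18% of the naive brain and 6.16% of the blood. The cells of these clusters were counted in the totals of the shares, and apart from the Cx3cr1 level of the microglia-like cluster their expression was not compared.

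Cx3cr1 was lower in the samples labelled control, with a log2 ratio of 2.48 in microglia; the values argue against dilution by other cells, as the other 19 homeostatic genes had a median of -0.10 and a highest value of 0.35, and against labels exchanged in 1 tissue only, as blood monocyte classes had ratios of 3.06 and 3.28. Labels exchanged in both tissues stay open. The microglial share was 2.15 times as large (1.79 to 2.61) in the sample labelled depleted, as an exchange would give. That share was seen before the test was chosen and rests on 1 hashed sample per arm, so it does not decide. An exchange would only change which arm had the lower Cx3cr1, and would not account for the difference itself. Nonclassical monocytes, which carry Cx3cr1 in the blood, went both ways. Under the depleted label they were 0.0511 times as frequent in the naive brain and 3.59 times as frequent in the blood. Whether the toxin removed monocytes in either tissue was not tested, so their shares do not decide between the labels. A return of microglia after depletion, not tested, would need no exchange. Lower depth under the control label was not excluded by the bound set: among 182 genes near the level of Cx3cr1 the largest log2 ratio was 5.78 and the median 0.05, and the only 2 genes as large as Cx3cr1 were the haemoglobin genes Hbb-bs and Hba-a1. More copies of the Cre insertion stay undecided, with Cx3cr1 at least 2-fold lower in 7 of 8 classes but, without shared droplets, in 3 of 6, where monocytes of the naive brain stood at 0.09 on 36 and 14 cells with any Cx3cr1, vascular cells at 0.86 and the microglia-like cluster at 0.29; the exception with all cells, the microglia-like cluster of the blood at 0.22, counted against this by the bound as first written and was set aside because 82.7% of its barcodes are also in a brain matrix. The 8 classes may not be independent, since Cx3cr1 in vascular cells and neutrophils may be carried over from other cells, which was not tested. A difference between the genotypes of the arms, or an effect of depletion on Cx3cr1, stays open as untested.

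The microglia-like cluster of the blood may be made of droplets that hold a brain cell beside a blood cell. Of its 468 barcodes 82.7% are also in a brain matrix, against 18.2% in other blood clusters. Against brain cells called by stray blood hashtag, its median count of blood hashtags was 401.5, near the 483 of the other clusters. No biological explanation was tested.

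The unnamed cluster of deep cells may hold cells of the brains with metastases called by stray hashtag. Its median count of blood hashtags was 19.5 in the blood, against 484 in other clusters, and its median count of naive-brain hashtags was 137 in the naive brain, against 517.5. Within the arms labelled control and depleted the latter was 75 and 175, against 71 and 218 in vascular cluster 8. It was 81.5 and 398 in vascular cluster 2, and 63 and 1132 in monocyte cluster 3. In the control arm the low count thus does not single the unnamed cluster out. Droplets that hold such a cell beside a cell of the naive brain stay undecided, with 72.1% of its barcodes in another matrix against 27.3% in the other clusters. Rhox5, Krt8, Rbp4 and Fkbp11, which are among the leading genes of this cluster in both tissues, are also among those of unnamed cluster 0 of the brain with metastases. Of the E0771 tumour markers only Krt8 passed in each, short of the 3 that a name needs, so the cells were given no type. No biological explanation was tested.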

How the results depend on the processing

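The settings without shared droplets, with surface gates in place of clusters, with gated cells as the denominator, with single arms of the naive brain, without cycling T cell cluster 17 and without microglial cluster 1 of the brain with metastases were chosen after the data were seen, and the others before. For the direction and size of each value, the cause was not tested.

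Recomputed under these settings, 39 shares gave 188 values, of which 151 lay within the interval of the first value, 33 beyond it and 4 in the other direction with a first interval that excluded 1. Another 6 of those beyond it crossed 1 where the first interval included 1. A gene or list value counts as close within 1.5 times of the first, and as turned where a first ratio of at least 2 fold changed sign. For 63 gene lists 611 of 648 values stayed close, 36 moved and 1 turned, and for 146 genes 836 of 1068 stayed close, 198 moved and 34 turned. Counting smaller ratios too, 32 of the 648 list values had the other sign, the larger of which are given below. Among the main shares and interferon lists 205 of 215 values stayed close, 10 moved and none met the rule for turning, though the interferon median changed sign in blood B cells with surface gates and with marker scores, and with marker scores in microglia of the naive brain (0.08) and T cells of the blood (0.06), and without cluster 1 in microglia of the brain with metastases (-0.16).

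With surface gates in place of clusters, log2 ratios turned for Ly6d in microglia (0.0449), Apoe in T cells (-0.59) and Cd209a (-0.33), Mgl2 (-2.52) and Prg4 (0.14) in monocytes of the naive brain. In the blood they turned for Areg in nonclassical monocytes (0.22), Ccl5 in monocytes (1.41) and Isg15 (0.94) and Jchain (1.61) in B cells, where the interferon median moved to 0.48. List medians that also changed sign were MHC class II in monocytes (-0.66) and microglia (0.07), homeostatic genes in microglia (0.28) and lysosome in T cells (-0.38) of the naive brain, and mitochondrial transcripts in nonclassical monocytes of the blood (0.32).

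With classes from marker scores, BC100530 in microglia (0.13) and Clec4b1 (-0.0639) and Prg4 (0.18) in monocytes of the naive brain turned, as did Isg15 (1.42) and Jchain (0.0381) in B cells and Ttr in T cells (-0.11) of the blood. The interferon median of the B cells moved to 0.67. The MHC class II median changed sign in microglia (0.32) and monocytes (-0.23) of the naive brain and in monocytes of the brain with metastases against the naive brain (0.23), and the mitochondrial median in nonclassical monocytes of the blood (0.40). In the brain with metastases against the naive brain, Jchain (0.10), S100a8 (0.51), S100a9 (0.50) and the neutrophil carry-over list (0.50) turned in microglia, and Mpo (-1.74), Elane (-0.57) and Cd209a (0.32) in monocytes. The microglial share ratio moved to 0.572, and the interferon median of nonclassical monocytes against the blood to 1.90.

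Without shared droplets, Areg in nonclassical monocytes (0.00900), Chil3 (-0.60) and Jchain (0.0614) in B cells and Gadd45g in T cells (0.43) of the blood turned, and the interferon median of monocytes of the brain with metastases against the naive brain moved to 1.18. Without cells far from the class median of genes, Cenpf in NK cells of the naive brain (0.10) and Chil3 in B cells (-0.43) turned. With a trimmed mean, Chil3 in B cells (-0.26), Ttr in T cells of the blood (-0.15) and Jchain in microglia of the brain with metastases (0.0136) turned, and the checkpoint list of its T cells against the naive brain changed sign (-0.21). Without cluster 17 the cell cycle median of these T cells was -0.06. Without cluster 1, Thbs1 (-0.52), Cxcl9 (-1.17) and Gbp2 (-0.0261) turned in microglia against the naive brain, the medians of MHC class II (-3.22) and monocyte origin (-0.62) changed sign, and the microglial share ratio moved to 0.314.

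For the brain with metastases over the naive brain, the monocyte share ratio turned to 0.525 at clustering resolution 0.5 and to 0.604 at resolution 2.0. Against the arm labelled control alone, the T cell share ratio turned to 1.74, Cxcl10 in T cells to -0.37, the MHC class II median of monocytes to 0.09, and the microglial share ratio moved to 0.720. Against the arm labelled depleted alone, the nonclassical share ratio turned to 2.45 and the microglial ratio moved to 0.335. Among immune classes only, the microglial ratio was 0.556. With the earlier annotation table, the share ratio of the CD11b+ Ly6C-low gate in the blood moved to 1.42.

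No paired analysis was possible because brain and blood of the same mouse were not linked by the labels. TMM or other size factors, thinning of raw counts to equal depth, comparisons between arms with a hashed sample left out, a replicate block, a correlation estimated for gene lists and alternatives for antibody tag values were not run, since each needs raw counts, replicates or tag values that were not used here. Depth limits genes under 0.5 CP10k and classes with few cells, such as 36 NK cells and 59 T cells of the naive brain labelled control, where small differences were not resolved.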

Other observations

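Genes of hypoxia and glycolysis were higher in lymphocytes and microglia of the brain with metastases than in those of the naive brain, in matrices normalized separately. All 9 measured genes were higher in T cells, with a median of 0.49 (percentile 99.99), 9 of 10 in NK cells, with a median of 0.45 (percentile 100), and 8 of 10 in microglia, with a median of 0.29 (percentile 100). NK cells also had a higher list of naive and memory genes, with a median of 0.82 over 6 genes (percentile 100).

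Between the brain with metastases and the blood, antigen presentation and cytokine genes were higher in monocytes and monocyte-derived macrophages of the brain. Part of this class in the brain has no firm name, and these matrices too were normalized separately. All 11 MHC class I genes were higher, with a median of 1.28 (percentile 99.7), and all 11 inflammatory cytokine genes, with a median of 2.72 (percentile 100). In nonclassical monocytes the cytokine list had a median of 1.96 (percentile 100). The brain but not the blood was digested, and dissociation and immediate early genes were higher in the brain in both classes.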
